A study of Homo sapiens with 2 samples.

How the data were processed

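CLIP-seq libraries of hTrmt13 from MDA-MB-231 cells were analysed, 1 group with 2 replicates. Per the labels' protocols, complexes were isolated with an antibody, the RNA was dephosphorylated and treated with AlkB-type enzymes to remove modifications, an adaptor was ligated, complexes were purified by SDS-PAGE and transfer to nitrocellulose, and cDNA was size-selected, circularized, cut and amplified by PCR. Without molecular identifiers, PCR reads are not independent molecules.

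The authors deposited whole-number read counts per listed feature, not normalized, in 1 table for each mate of each library, 4 tables in all. Per the submitters' processing notes, Bowtie2 2.3.5.1 and bedtools 2.24.0 were used with the hg19 (GRCh37) build. Alignment options, the treatment of reads with several matches, and whether strand was used are not given in the sources used here. The tables point to counting on both strands in most cases: of 32 pairs of a tRNA feature with at least 1000 R1 counts in replicate 1 and an overlapping feature on the other strand, the feature held at least the tRNA's count in 30. That count minimum was chosen after the data were seen. Some of these features also overlap tRNA features on their own strand, so those pairs tell less, and they were not counted apart. LTA4H overlaps only 1 tRNA feature, on the other strand. It held 81536 R1 counts in replicate 1 against 81404 for that tRNA. Each table lists 741091 features. After 13 repeated lines were dropped, 741078 remained, among them 596 tRNA features (549 tRNA genes and 47 tRNA lookalikes), 20298 protein-coding genes and 679820 piRNAs. No hg19 annotation was used here, so exons, introns and UTRs are not given. Positions are from the tables and 1-based. All 37 mitochondrial features had the 1-based positions of GENCODE release 29, so those starts were kept. Of 452 tRNA genes matched by symbol to RefSeq, 435 had the RefSeq length when the start was read as 0-based and 0 when it was read as 1-based, so 1 was added to tRNA and piRNA starts. The 4 ribosomal DNA features had no counts.

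Shares of the library total and CPM were computed from the R1 table, with exact Clopper-Pearson 95% intervals for single libraries. The R2 totals were 40.3% and 42.7% of the R1 totals. tRNA counts were summed by anticodon and isotype. Percentiles of gene lists were taken from the median log2(CPM + 0.5) among 10000 random lists of the same size, matched on biotype and length decile, for features with a mean count of at least 10. The coefficient of variation came from edgeR 4.0.16 (TMM factors, common dispersion of a 1-group design) in R 4.3.3, with DESeq2 1.42.0 size factors as an alternative. The split of each feature between the libraries was tested by an exact two-sided binomial test, adjusted by Benjamini-Hochberg at 0.05. With 1 group, no test between conditions was possible. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Replicates of 18723 features with 200 changed were simulated with counting (Poisson) error only. On these the binomial test recovered 68% of the 2-fold and 100% of the 4-fold changes and called 0.027% of unchanged features. That simulation held no spread between libraries, whereas the real libraries had a coefficient of variation of 0.192. Its rate of false calls therefore does not carry over to them. In a separate simulation, a coefficient of variation of 0.2 was estimated as 0.203. Of 40 simulated lists of 30 protein-coding genes raised 2-fold, 97.5% lay above percentile 97.5, and 5% of unchanged lists lay outside the central range.

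The genes named in the text follow a rule set before the data were examined: the 15 features with the highest mean CPM of any biotype, the 15 highest protein-coding genes, the 10 highest protein-coding genes per kilobase, the 10 highest non-coding genes outside tRNA, rRNA and mitochondrial features, the Gly, His and Pro anticodon families and the 5 other highest families, the 5 features differing most between replicates in each direction, TRMT13, and the 2 to 4 highest members of each list. From these the text gives examples. SACM1L, SHF, MT-TE, RGPD2, MT-TK, MARCH5, CDH1, KRT18, EPCAM, KRT8 and SPARC lie outside this rule and were chosen after their values were seen. The gene lists, the tests in the main results and most alternative settings were set before the data were examined. These settings were the R2 table, the sum of both mates, each replicate left out, minimum mean counts of 1 or none, other denominators, features inside another class left out, tRNA lookalikes left out, the highest gene of each isotype left out, counts per tRNA gene or per kilobase, all features for length, and other scalings. The alternatives added after the data were seen were the subtraction of tRNA counts from overlapping features (2 features fell below 0 and were set to 0) and leaving out the highest gene of each anticodon family.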

Results

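RNA bound to hTrmt13 (TRMT13), the human relative of the yeast tRNA 2'-O-methyltransferase Trm13, was measured by CLIP-seq in MDA-MB-231 cells, an established human breast carcinoma line. In CLIP-seq, complexes of a protein with crosslinked RNA are isolated with an antibody and the RNA is sequenced. The series' stated purpose for this assay was to find the tRNAs bound by the enzyme. There was 1 group with 2 replicates, and 0 input or antibody control libraries were analysed here, so a share of counts describes what was recovered and not an enrichment over background. Each replicate had 1 count table for each of its 2 read mates (R1 and R2). The R1 tables held 27907799 counts in replicate 1 and 20590398 in replicate 2, and the R2 tables held 11246823 and 8793089. Values are from R1 unless stated. The labels do not say whether the replicates came from separate cultures, so the SD may reflect technical spread only. Intervals cover counting error only.

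Cytosolic tRNA was the most abundant RNA class. It took 58.2% ± 2.59 (SD, n = 2) of the counts, with 60.02% in replicate 1 (95% Clopper-Pearson interval 60.004 to 60.040%) and 56.4% in replicate 2. Nuclear protein-coding genes took 29.4% ± 1.59 (SD, n = 2), long non-coding RNA genes took 8.13% ± 0.523 (SD, n = 2), and the 22 mitochondrial tRNAs took 1.55% ± 0.0241 (SD, n = 2). Reads of a tRNA feature (a tRNA gene or lookalike) were in most cases also counted in the features that overlap it, on either strand, and 154 listed features overlap a tRNA feature, 130 of them a tRNA gene and 24 only a tRNA lookalike. SACM1L, with 98 counts in replicate 1 against 3393 for its tRNA, and SHF, with 5226 against 18714, were exceptions. The 154 features held 30.5% of the counts of replicate 1 and 27.3% of those of replicate 2. Within the protein-coding class they held 80.8% and 65.0% of the counts. When the counts of the overlapped tRNA features were taken off, an alternative chosen after the data were seen, cytosolic tRNA took 81.9% ± 6.22 (SD, n = 2) and nuclear protein-coding genes took 11.3% ± 4.88 (SD, n = 2). Long non-coding RNA genes then took 2.12% ± 0.749 and mitochondrial tRNAs 2.17% ± 0.0346 (SD, n = 2 each). When every feature lying inside a feature of another class was left out instead, the share of cytosolic tRNA was 45.8%. That setting drops tRNA features inside genes but keeps their reads in the genes around them, so 45.8% is not a lower bound for tRNA.

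**Figure D1:**
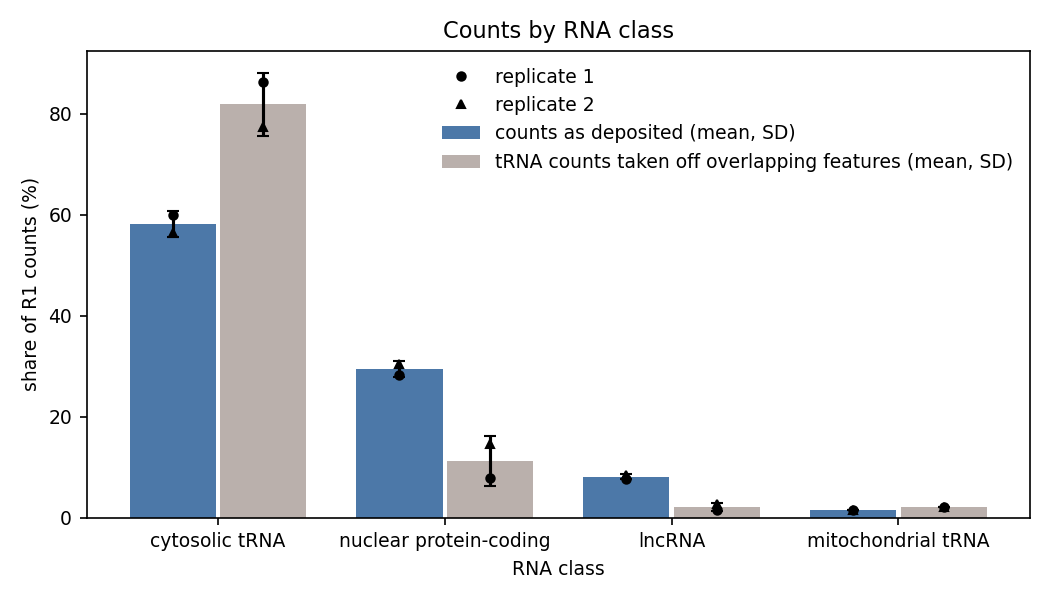
Share of R1 counts (%) of 4 RNA classes, as deposited and after tRNA counts were taken off overlapping features. Bars are means, error bars are SD of the 2 libraries and symbols are single libraries; cytosolic tRNA stood at 58.2% as deposited and 81.9% after subtraction.

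Arginine, lysine and threonine tRNAs led the cytosolic tRNA counts. tRNA-Arg took 32.4% ± 1.12 (SD, n = 2) of these counts while making up 5.54% of the 596 tRNA features. tRNA-Lys took 26.7% ± 1.11 (SD, n = 2) against 7.72% of the features, and tRNA-Thr took 11.8% ± 0.235 (SD, n = 2) against 3.69%. In R2 the order of the leading isotypes changed, with tRNA-Lys at 41.2% ± 1.40 (SD, n = 2) and tRNA-Arg at 14.5% ± 0.329 (SD, n = 2). Both shifts between mates were larger than the spread between replicates. The change of order rested on 1 locus, tRNA-Lys-TTT-14-1. It held 2070520 of the 2873755 tRNA-Lys counts of R2 in replicate 1 and 1478392 of 2031190 in replicate 2. The other tRNA-Lys features together held fewer R2 counts than tRNA-Arg, which had 1052030 and 686353. By anticodon, Arg-CCT led with 23.8% ± 1.25 (SD, n = 2), followed by Lys-TTT with 18.3% ± 0.374, Thr-TGT with 7.94% ± 0.0323, Lys-CTT with 6.26% ± 0.685 and Asn-GTT with 3.86% ± 0.247.

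**Figure D2:**
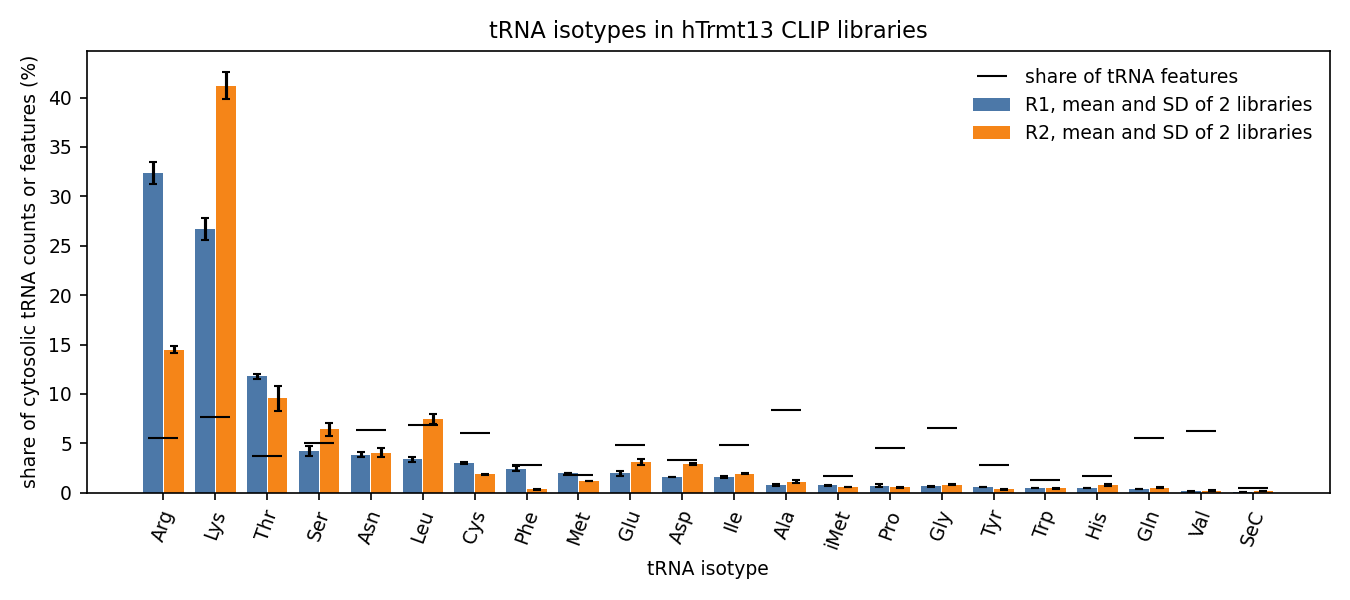
Share of cytosolic tRNA counts (%) for each tRNA isotype in R1 and R2 (bars, mean; error bars, SD of 2 libraries), with the share of tRNA features as black dashes. Arg, Lys and Thr lay above their share of features in both mates, while Gly, His and Pro lay below theirs.

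A few gene copies carried most of the tRNA counts. The 3 highest loci held 35.4% of them and the 20 highest held 62.2%, out of 547 tRNA features with a count. On the hg19 build, tRNA-Arg-CCT-2-1 (chromosome 17, 73030526 to 73030598, minus strand) took 16.1% ± 0.0319 (SD, n = 2) of tRNA counts and lies within the span of KCTD2. tRNA-Lys-TTT-14-1 (chromosome 14, 74055529 to 74055607, minus strand) took 12.8% ± 0.276 (SD, n = 2) and lies in no other listed feature. tRNA-Arg-CCT-4-1 (chromosome 7, 139025446 to 139025518, plus strand) took 6.43% ± 1.14 (SD, n = 2) and lies within LUC7L2 and C7orf55. Counts of single tRNA loci are uncertain, because copies of a tRNA share most or all of their mature sequence. The mates also differed by locus. For tRNA-Lys-TTT-14-1 the R2 count was 97.7% of the R1 count in both replicates, whereas for tRNA-Arg-CCT-2-1 it was 17.9% in replicate 1 and 16.0% in replicate 2.

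Yeast Trm13 methylates glycine, histidine and proline tRNAs, so the human families of these isotypes were compared with the rest. Together they took 1.84% ± 0.274 (SD, n = 2) of tRNA counts while making up 12.8% of tRNA features, a ratio of 0.145. Most isotypes lay below their share of features, since only Arg, Lys, Thr and Met exceeded it in R1. Ala (0.0912), Gln (0.0702) and Val (0.0225) had lower ratios than these 3 isotypes together. tRNA-Gly took 0.636% ± 0.0950, tRNA-His 0.485% ± 0.0476 and tRNA-Pro 0.722% ± 0.132 (SD, n = 2 each). The families from highest to lowest were His-GTG (0.485% ± 0.0476), Pro-TGG (0.388% ± 0.0848), Gly-GCC (0.319% ± 0.0334), Pro-AGG (0.243% ± 0.0359), Gly-TCC (0.201% ± 0.0321), Gly-CCC (0.116% ± 0.0296) and Pro-CGG (0.0916% ± 0.0110). Of these 7 families, 0 lay above the median of the 49 anticodon families with a mean count of at least 10. Another family of these isotypes, Pro-GGG, had 0 counts and fell below that minimum. The median of the 7 stood at percentile 8.23 among 10000 random sets of as many families, with 6.07 in replicate 1 and 8.23 in replicate 2. The percentile describes these libraries and is not a test. It was 4.55 in R2, 4.47 with counts per tRNA gene and 20.8 when the highest gene of each family was left out, the last chosen after the data were seen.

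The protein-coding genes with the highest counts were mostly features that overlap a tRNA gene. Of the 15 with the highest mean library-scaled count (CPM), 12 overlapped a listed tRNA gene. KCTD2 (ENSG00000180901.10_2, chromosome 17, 73028670 to 73061984) stood at 95211 ± 4423 CPM (SD, n = 2), and 6.95 ± 2.63 CPM remained after subtraction of its enclosed tRNAs. CPM after subtraction are scaled to the smaller totals left, 19419151 counts in replicate 1 and 14980913 in replicate 2. LUC7L2 (ENSG00000146963.17_3), a splicing factor gene, went from 37574 ± 8300 to 23.3 ± 9.89 CPM (SD, n = 2). MORF4L1 and NDUFS7, which encodes a subunit of respiratory complex I, went from 7505 ± 622 to 6.74 ± 4.44 CPM and from 7065 ± 614 to 5.47 ± 2.93 CPM. The 3 without a listed tRNA were KIF5C (4271 ± 457 CPM), KIAA0825 (1369 ± 175 CPM) and AKAP6 (1168 ± 66.4 CPM) (SD, n = 2 each). In R2, KIF5C stood at only 19.7 ± 3.20 CPM, KIAA0825 at 4485 ± 292 CPM and AKAP6 at 1455 ± 112 CPM. Nearly all KIF5C counts of R1 were also counted in AC105402.4, which overlaps it on the other strand. All 15 features with the highest CPM of any biotype were tRNA features or features overlapping one, at 9 and 6 features. Among the 10 highest non-coding genes outside tRNA, rRNA and mitochondrial features, 7 overlapped a tRNA gene and RP11-61O11.1, the highest at 11380 ± 361 CPM, only a tRNA lookalike. It was followed by RP11-867G23.8 at 11184 ± 1091 CPM and RP11-217B1.2 at 11088 ± 834 CPM (SD, n = 2 each). The lead of RP11-61O11.1 held in R1 only. In R2 it stood at 45.5 ± 1.09 CPM, RP11-867G23.8 at 22799 ± 3797 CPM and RP11-217B1.2 at 6690 ± 139 CPM. TRMT13 itself (ENSG00000122435.9_2; chromosome 1, 100598706 to 100616053) had 45 counts in replicate 1 and 67 in replicate 2, or 2.43 ± 1.16 CPM (SD, n = 2).

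Mitochondrial tRNAs were recovered from all 22 genes, with a median of 441 CPM. MT-TS2 stood at 1880 ± 118 CPM, MT-TF at 1849 ± 147 CPM, MT-TI at 1826 ± 58.0 CPM and MT-TQ at 1810 ± 52.4 CPM (SD, n = 2 each). The 13 mitochondrial mRNAs had a median of 56.5 CPM, led by MT-CO1, a subunit of respiratory complex IV, at 292 ± 110 CPM (SD, n = 2), and their list median stood at percentile 100 among random lists.

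Gene lists fixed beforehand were placed among 10000 random lists of equal size matched on feature length and biotype, as a description without a test. The random lists were not matched on RNA level in the cells, so a percentile does not separate recovery by hTrmt13 from RNA abundance. The list medians of the 79 cytosolic ribosomal protein genes and the replication-dependent histone genes stood at percentile 100. So did those of the abundant cytoplasmic mRNAs and of the long non-coding RNAs listed as nuclear-retained. The location of the latter in these cells was not measured. RPS2 stood at 47.4 ± 27.1 CPM and RPL3 at 39.7 ± 23.0 CPM. RPS29 had the highest ribosomal protein value, 379 ± 259 CPM, but its span encloses the 7SL RNA gene RN7SL1, which held 5406 of its 5488 counts in replicate 1. HIST1H1C, a linker histone, stood at 33.8 ± 21.9 CPM, MALAT1 at 90.0 ± 33.5 CPM, and EEF2, a translation elongation factor, at 198 ± 118 CPM (SD, n = 2 each). The 20 aminoacyl-tRNA synthetase genes, whose products charge tRNAs with amino acids, had a median of 9.80 CPM and stood at percentile 99.99, with IARS at 33.1 ± 17.8 CPM and EPRS at 18.96 ± 10.7 CPM. The list of tRNA modification and processing enzymes stood at percentile 32.6, with WDR4 at 9.62 ± 4.94 CPM and ELAC2 at 8.67 ± 4.91 CPM. This list as fixed holds MARCH5, which is not a tRNA enzyme, and its percentile was 91.3 on counts per kilobase.

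The list of genes of the epithelial to mesenchymal transition (EMT) stood low in R1. It mixes EMT factors and mesenchymal genes with epithelial markers. The markers CDH1 (1.96 CPM), KRT18 (1.58), EPCAM (1.01) and KRT8 (0.941) lay below 2.76 CPM, the median of members past the count minimum. So did some mesenchymal members, such as SPARC at 1.21 CPM. No percentile was computed without the epithelial markers, so the low place is not shown for mesenchymal genes alone. Of the 32 on the list, 24 had a mean count of at least 10, and their median stood at percentile 3.42 in R1, with 1.31 in replicate 1 and 5.03 in replicate 2, but at 29.8 in R2. VIM, which encodes the intermediate filament vimentin, stood at 24.4 ± 15.1 CPM, TGFB1 at 16.8 ± 10.5 CPM and ZEB1, a transcription factor, at 11.0 ± 3.76 CPM (SD, n = 2 each). Markers of blood, liver and neuronal cells, included as background genes, had a median of 0.139 CPM over 15 genes. The 4 of them with a mean count of at least 10 stood at percentile 10.3, with 16.4 in R2 and 27.4 on counts per kilobase. RBFOX3, the highest, stood at 1.74 ± 1.25 CPM. Among small nuclear and 7S RNAs, RN7SL2 stood at 429 ± 317 CPM, RPPH1, the RNA of ribonuclease P, at 291 ± 198 CPM, and RN7SK at 259 ± 114 CPM (SD, n = 2 each). Small nucleolar and Cajal body RNAs were sparse. Of 841 listed, 516 had no count in either R1 table, and SNORD3A led with 15.04 ± 1.66 CPM (SD, n = 2). No percentile was computed for the small nuclear, small nucleolar and mitochondrial tRNA lists, because in at least 1 of the biotype and length classes of each list too few other features past the count minimum remained to draw from. Longer protein-coding features had higher counts, with Spearman's rho of 0.401 in replicate 1 and 0.350 in replicate 2 across 13220 genes, which are not independent replicates.

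The 2 replicates ranked features alike but differed in their balance of tRNA to mRNA. Across 18723 features, which are not independent replicates, Pearson's r of log2(CPM + 0.5) was 0.977 and Spearman's rho was 0.959, and the biological coefficient of variation was 0.192. An exact binomial test with Benjamini-Hochberg adjustment found 1580 features whose counts departed from the ratio of TMM-scaled library sizes, 400 higher and 1180 lower in replicate 2. This test compares 1 library with 1 other and not conditions, and it covers the counting error of PCR reads only, not the spread between libraries. Under TMM scaling cytosolic tRNA had a median log2 ratio of replicate 2 over replicate 1 of -1.10, and 428 of 473 tRNA features passed the test as lower. Mitochondrial tRNAs had a median of -1.10 (22 of 22 lower) and small nuclear RNAs a median of -1.29, while nuclear protein-coding genes had a median of 0.01. With scaling to total counts the medians were -0.01 for cytosolic tRNA, -0.01 for mitochondrial tRNAs (8 higher and 7 lower), -0.19 for small nuclear RNAs and 1.11 for nuclear protein-coding genes. Of the 15279 features that then passed, 15014 were higher in replicate 2. Going from one scaling to the other shifts every feature by the same 1.09 on the log2 scale, so these data give the difference between classes but not which class changed. Among single features, APOBEC3A, a cytidine deaminase gene, had 74 counts in replicate 1 and 1993 in replicate 2. These counts cover its listed span (chromosome 22, 39348746 to 39388783), and where in it they lie is not known. APOBEC3G had 0 and 25. CTA-150C2.16, which overlaps the end of APOBEC3A, had 0 and 49. In the other direction, CHI3L2 had 38 counts in replicate 1 and 1 in replicate 2, MX2 had 27 and 3, and RNU5B-1, a small nuclear RNA of the spliceosome, had 426 and 83.

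**Figure D3:**
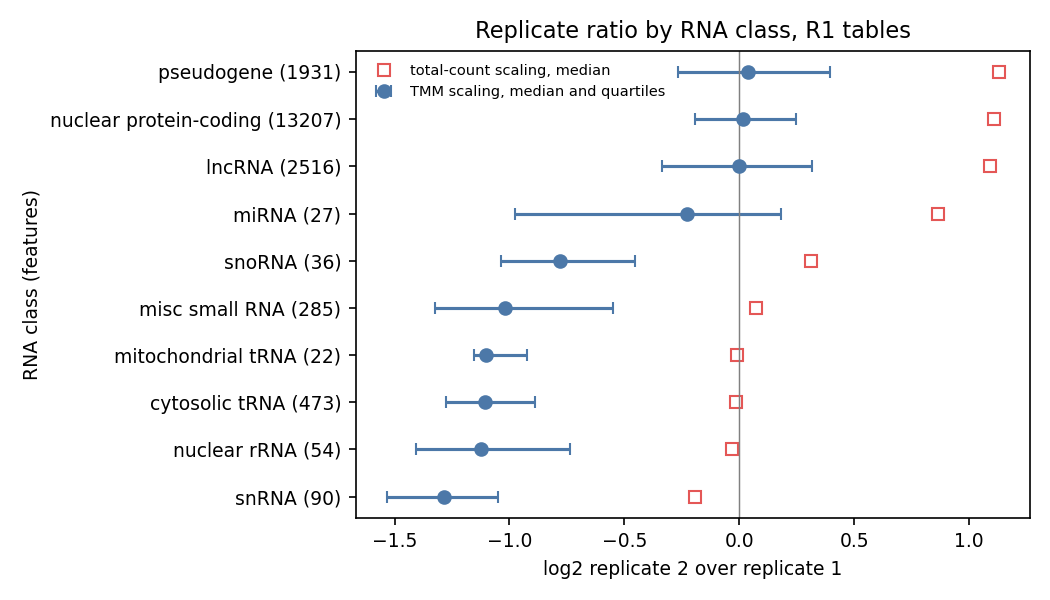
Log2 ratio of replicate 2 over replicate 1 by RNA class in the R1 tables, for classes with at least 20 features, leaving out the TEC biotype. Filled circles with bars are medians and quartiles under TMM scaling and open squares are medians under total-count scaling; cytosolic tRNA lay at -1.10 and nuclear protein-coding genes at 0.01 under TMM.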

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

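Of 189 values of the comparisons under an alternative setting, 123 moved by less than 1 SD of the 2 replicates and 66 by more. A mean of 2 libraries always moves by less than 1 SD when either is left out. Class and isotype shares with a replicate left out therefore could not count as moved, and they are no sign of stability. Counts of features were compared within 1.5 times, and the coefficient of variation and correlations, which have no SD, within 1.1 times, a bound chosen after the data were seen. The cause of the shifts was not tested, except where the setting itself removes the counts. Of 420 CPM values of named features, 152 moved by more than 1 SD, 104 up and 48 down. No paired analysis was possible because there was 1 group. What depth limits was not tested: replicate 1 had the larger R1 total but fewer features with a count, 51331 against 60280. The subtraction of tRNA counts and leaving out the highest gene of each family were chosen after the data were seen.

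In R2, the share of nuclear protein-coding genes was 26.7%, of lncRNA 8.97% and of mitochondrial tRNA 1.66%, and the sum of mates gave 1.58% for the last. With the 10 highest features left out of the total, nuclear protein-coding took 21.3%, lncRNA 12.1% and mitochondrial tRNA 2.69%. Leaving out features inside another class keeps tRNA reads in the features around them. Cytosolic tRNA then took 45.8%, nuclear protein-coding 39.1%, lncRNA 10.2% and mitochondrial tRNA 2.06%. With tRNA counts subtracted they took 81.9%, 11.3%, 2.12% and 2.17%.

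In R2, Gly, His and Pro together took 2.14% of tRNA counts, Arg 14.5%, Lys 41.2%, Thr 9.55%, Gly 0.807%, His 0.759% and Pro 0.571%. The sum of mates gave Arg 27.1%, Lys 31.0%, Thr 11.1% and His 0.566%. Without the highest gene of each isotype, Gly, His and Pro together took 2.47%, Arg 26.8%, Lys 22.8%, Thr 15.4%, Gly 0.934%, His 0.585% and Pro 0.9498%. Without lookalikes and undetermined anticodons, Lys took 25.1% and Thr 12.1%. The percentile of the Gly, His and Pro families was 4.55 in R2, 11.4 with a minimum mean count of 1, 4.47 with counts per tRNA gene and 20.8 without the highest gene of each family, and it ranged from 6.07 to 8.23 with either replicate left out.

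The binomial test found 15279 features with scaling to total counts and 3589 in the sum of mates. With scaling to total counts the coefficient of variation was 0.525, and the median feature shifted by 1.09 on the log2 scale. With no minimum count, Spearman's rho between replicates was 0.574. The rho of length was 0.510 with no minimum count and 0.325 over all features.

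The EMT percentile was 29.8 in R2, 6.16 with a minimum mean count of 1 and 20.4 with no minimum count. The tRNA enzyme percentile was 20.7 in R2, 45.9 in the sum of mates, 83.6 with a minimum of 1, 95.9 with no minimum and 91.3 on counts per kilobase, and ranged from 38.03 to 46.7 with either replicate left out, so its place among random lists depends on these settings. The synthetase percentile was 100 in R2, in the sum of mates, with a minimum of 1, with no minimum count and with tRNA counts subtracted, 99.97 on counts per kilobase, and 99.98 to 99.99 with either replicate left out. The percentile of other cell types' markers was 16.4 in R2, 5.37 in the sum of mates, 3.84 with a minimum of 1 and 27.4 on counts per kilobase. The other 5 lists stayed at 100 in all settings run.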

Other observations

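The tests that weigh explanations in this part were chosen after the values they bear on had been seen, while the binomial test and the gene lists were set before. The binomial test compares 1 library with 1 other and covers counting error only. In the list of small nuclear and 7S RNAs, 24 of 34 tested members were lower and 4 higher in replicate 2 under TMM scaling, and 5 were lower and 8 higher under total scaling. Of its 4 highest members, RN7SL2 had a log2 ratio of 0.58, RN7SL1 0.43, RPPH1 0.41 and RN7SK -0.17 under TMM, whereas all 4 had higher CPM in replicate 2 under total scaling, RN7SK with 178 and 339. Under TMM, 22 of 79 tested ribosomal protein genes passed the binomial test as higher in replicate 2 and 0 as lower, and 14 and 0 of 57 tested histone genes did. Of the 22 abundant cytoplasmic mRNAs tested, 10 passed as higher and 0 as lower, so the direction is not particular to the first 2 lists. Under total scaling 79, 55 and 21 passed as higher, as did 15014 of all 18723 features. The ribosomal protein genes higher under TMM include RPS29, nearly all of whose counts are also counted in RN7SL1. Of the 13 mitochondrial mRNAs 0 passed as higher and 10 as lower under TMM and 13 as higher under total scaling, with median log2 ratios of -0.35 and 0.74. KIF5C had 110173 R1 counts and 196 R2 counts in replicate 1.

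The Gly, His and Pro tRNAs lay below their share of tRNA features, which was 12.8%, but so did most isotypes, and Ala, Gln and Val lay further below, so the deficit is not particular to these 3. The choice of mate as the cause is argued against by the highest share in any of the 4 tables, 2.28%. A single high gene copy per isotype is argued against as well, since the share was 2.47% without the highest gene of each isotype, against 12.8% of the features left. The level of each tRNA in the cells may set these shares and stays open, because 0 input or control libraries were analysed here. No biological explanation was tested.

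Of the gene copies that share 1 mature tRNA sequence, only those with at least 100 R1 counts in both replicates were compared. In 26 of 53 isodecoders with at least 2 such copies, the R1 counts of the copies differed by more than 2-fold in both replicates, and among these the fold range of R2/R1 between copies had a median of 4.16 in replicate 1 and 4.36 in replicate 2. Different output of the copies alone would leave R2/R1 alike. In 16 of the 26, R2/R1 differed by more than 2-fold in both replicates. There, different output is argued against as the whole cause of the counts in both mates. This does not tell what set the R1 differences, since R2/R1 also differed where R1 counts were alike. In tRNA-Thr-AGT-1 the R1 ranges were 1.17 and 1.18, and the R2/R1 ranges 13.2 and 11.2. Of all 53 isodecoders, 23 passed 2-fold in R2/R1 in both replicates. In the other 10 of the 26, median ranges were 1.34 and 1.28 for R2/R1 but 8.30 and 6.59 for R1, and different output stays open. The bound of 2 was settled after the values were seen. Over all 53 isodecoders the medians were 1.71 and 1.69. The 2 looser bounds, 100 and the median R1 range of 10.8, were tried and given up. Chance amplification in 1 library is argued against by how far each copy's log2 R1 count lay from its isodecoder's mean: with isodecoders picked on 1 replicate alone, Spearman's rho between the replicates was 0.996 with either pick, over 114 and 113 copies, which are not independent. Amplification bias shared by both libraries, or how reads with several matches were assigned to copies in each mate, may account for the rest, and neither was tested.

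KIAA0825 had 34771 R1 counts in replicate 1 without a listed tRNA in its span. Its counts lay within 0.385% of those of the mitochondrial tRNA MT-TE in all 4 tables, and it was the only 1 of 34 nuclear protein-coding features without a listed tRNA and with at least 1000 counts that lay within 5% of a mitochondrial tRNA, a bound chosen after the values were seen; RGPD2 lay just outside it, within 5.52% of MT-TK. This is consistent with reads shared with a nuclear copy of that tRNA, which may be counted at both places; no hg19 sequence was used to look for the copy. An ordinary transcript is argued against by its R2/R1 of 1.38 in replicate 1 and 1.34 in replicate 2, against upper bounds of 1.01 and 0.973 for the central 95% of 4078 nuclear protein-coding features without a listed tRNA and with at least 100 R1 counts in both libraries. No biological explanation was tested.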
